A study of Drosophila melanogaster with 9 samples.

How the data were processed

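RNA was measured in developing eyes of Drosophila melanogaster pupae, dissected 40 to 41 hours after puparium formation at 25 °C. According to the labels, each library came from 60 pooled eyes and 100 ng of total RNA, was made with a poly(A) selection kit and was read as pairs of 150 nt on an Illumina HiSeq instrument. The pGMR-GAL4 driver, which is active in the differentiating eye, expressed a control mCherry transgene, an mCherry-tagged Bonus (Bon) transgene, or that Bon transgene together with an RNAi construct against yorkie (yki). The series design names 3 biological replicates for each of the 3 conditions, 9 libraries in all. Groups and replicate numbers were taken from the sample titles.

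The authors deposited 1 table of counts per gene for each library. Per the submitters' processing notes, cutadapt 2.9, Bowtie2 2.3.5.1, STAR 2.7.0e, featureCounts from Subread 1.6.2, DESeq2 1.30.1 and the genome build BDGP6 were used. The role and options of each tool, the strandedness of the libraries and the handling of reads shared between genes are not given in the sources used here. Per the file headers, each row holds a gene identifier, exon positions, strand, length, name, biotype and a count. The deposited values are estimated counts that need not be whole: between 39.7 and 42.8% of the values in a library had a decimal part. Where the decimals come from was not tested. If reads shared between overlapping genes or near-identical copies were divided, the values of such genes are uncertain, for example the Hsp70 copies and the tal-1A, tal-2A and tal-3A products of 1 transcript. Reads of a gene and of its antisense partner may likewise have been mixed. The authors also deposited a table for each of 2 comparisons, with size-factor-scaled counts (a signal per library), a fold change as a ratio, a log2 fold change, a p-value and an adjusted p-value, per the file headers. No value of those tables entered the tests. What is quoted from them is named as the authors'.

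The counts were rounded to whole numbers before testing. Each table held 17558 genes, of which 17252 were matched to a current symbol through an identifier table. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10) in R 4.3.3, which left 11068. Libraries were scaled by TMM factors (0.961 to 0.968 in mCherry, 0.991 to 1.01 in Bon, 1.03 to 1.04 in Bon+yki-RNAi). Expression is given as CPM, counts scaled to the TMM-adjusted library size, as mean ± SD over 3 libraries. The quasi-likelihood test of edgeR (robust fit, group as the only term, all 9 libraries in 1 fit) gave log2 fold changes and two-sided p-values, adjusted over all tested genes by the Benjamini-Hochberg method. The threshold was an adjusted p of 0.05, and every adjusted p of a gene is from that test unless another is named. The ± after a log2 fold change is its standard error, taken as the fold change divided by the square root of the F statistic. Each group had n = 3.

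Gene lists were tested with camera of limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01 between genes, and adjusted over the 32 lists of each comparison. Lists with at least 3 tested members were used. The counts of members past the gene test are given as adjusted over all genes and as adjusted over the list alone. Camera with a correlation estimated for each list, and fry, were run beside it. Several lists share members. The lists, the tests, the groups, the alternative settings and the rule for named genes were set before the data were examined. The rule named bon and yki, and the 8 largest rises and 8 largest falls per comparison among genes past the threshold with non-overlapping libraries, a mean of at least 5 CPM and a proper gene name. It also named at most the 4 members of each list with the smallest p, and for genes changed in opposite directions 6 genes per direction under the same filters. For length, the text gives the 3 members with the smallest p for lists past the list test and the 2 with the smallest p for other lists, and in the third comparison bon, yki and the first 3 of each direction. This shortening was chosen after the data were examined and goes by rank alone. Genes outside the rule are marked as chosen after their values were seen. Gene positions are those of the deposited tables, in BDGP6.

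The comparisons of Bon with mCherry and of Bon+yki-RNAi with Bon share the Bon libraries. Their overlap was therefore set beside 20 simulations of unchanged groups, and beside the number expected of independent lists. The 3 Bon libraries were too few to be divided between the comparisons.

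Depth ranged from 34926438 to 48524961 counts per library. At these depths 3 counts, the smallest number told apart from 0 here, correspond to 0.0618 to 0.0859 CPM before scaling, which covers counting error only. Where a group mean of a named gene lay at or under that level, with counts present, an exact binomial 95% interval of the log2 ratio of summed counts is given as a counting interval, with the same limit. The common dispersion was 0.00129. The test was run on simulated counts with 200 changed genes per comparison. For Bon against mCherry, with 10807 genes, it recovered 52% of the changes at a fold of 1.2, 80% at 1.5, 92% at 2 and 96% at 4, and 6 of 166 calls were false. For Bon+yki-RNAi against Bon, with 10855 genes, the shares were 60, 86, 94 and 98%, and 8 of 177 calls were false. These simulations changed only 200 genes, in random directions, while 52.4% of genes were past the threshold for Bon against mCherry in the data. Counts were drawn with the dispersion of the fit alone, as in the 20 simulations of unchanged groups. Error rates under a shift in scaling or a wider spread of replicates are therefore not covered. In a simulation of lists with genes drawn independently, 1 moved list was called and 0 of 20 unmoved lists were. It does not cover lists of correlated genes, and in the data the estimated correlation reached 0.53 (muscle markers).

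Alternatives were the size factors of DESeq2 1.42.0 and upper-quartile factors in the edgeR fit, the Wald test of DESeq2, no low-count filter, a fit over the 6 libraries of a comparison, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. Counts and lists without genes of chromosome 3, and lists without y and v, were added after the data were seen. The main tests used every library and every gene past the filter.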

Results

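The data set holds 9 RNA-seq libraries of pupal eyes, 3 for each genotype: an mCherry control, eyes that overexpress Bon, and eyes that overexpress Bon while yki is knocked down. Bon is a transcriptional cofactor of the TIF1 family, and Yki is the transcriptional coactivator that the Hippo pathway restrains. Epidermal trichomes start to appear in Bon-overexpressing eyes at this stage, per the series design, and the comparisons ask which genes respond to Bon and which of these responses need yki. Library totals were 34926438 to 48524961 counts in mCherry, 38754394 to 48485542 in Bon and 37137136 to 39690537 in Bon+yki-RNAi. Log CPM values of libraries within a group correlated at 0.996 or more across genes, and every pair within a group differed by more than counting noise (chi-square per gene of 2.64 to 11.3). The first principal component held 71.9% of the variance and the second 15%.

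The targeted genes were examined first. The gene bon (FBgn0023097, BDGP6 3R, 20593139 to 20612540) stood at 174 ± 2.94 CPM in mCherry eyes, 4980 ± 258 CPM in Bon eyes and 4170 ± 48.1 CPM in Bon+yki-RNAi eyes (SD, n = 3). Its log2 fold change was 4.84 ± 0.04 with Bon (edgeR quasi-likelihood adjusted p = 2.38e-18). It was slightly lower again in Bon+yki-RNAi than in Bon, at -0.26 ± 0.03 (adjusted p = 6.14e-05). The gene yki (FBgn0034970, 2R, 24065975 to 24068485) stood at 61.1 ± 1.46, 62.6 ± 0.316 and 29.2 ± 0.25 CPM in the same order. Bon left it at 0.04 ± 0.03 (adjusted p = 0.33), although with upper-quartile scaling this became 0.10 with an adjusted p of 0.00783. The RNAi construct lowered yki by -1.1 ± 0.03 on the log2 scale (adjusted p = 8.29e-12). In the authors' deposited tables the log2 fold changes of bon were 4.85 and -0.25, and those of yki 0.04 and -1.09.

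**Figure D1:**
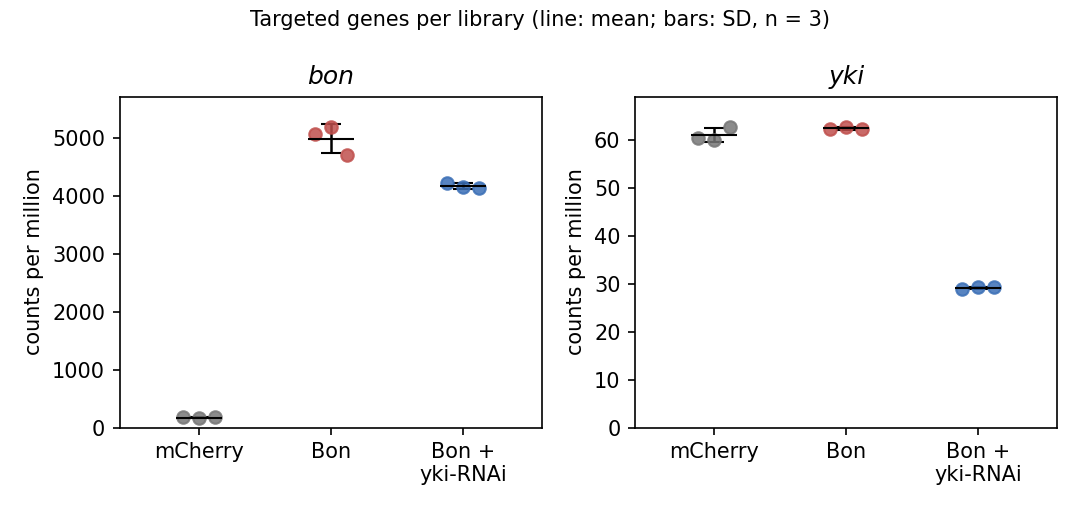
CPM of bon (left) and yki (right) in each of the 9 libraries, with points for libraries, lines for group means and bars for the SD (n = 3). The Bon libraries lie between 4700 and 5190 CPM for bon against 170 to 176 CPM in mCherry, and yki lies at 28.9 to 29.3 CPM in the knockdown libraries.

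With Bon overexpression, 15 of 21 eye pigment genes and 4 of 4 lens genes fell, and some genes rose from near absence. As lists, both passed the camera test with a preset correlation but not with an estimated correlation (adjusted p = 0.298 for each). The largest falls by the naming rule were in the cuticle protein genes Vajk2, from 215 to 0.559 CPM (log2 fold change -8.54 ± 0.12, adjusted p = 1.58e-12), and Vajk3 (-8.09 ± 0.21), and in vermilion (v), which encodes the first enzyme of brown eye pigment synthesis, from 59.3 to 0.223 CPM (-8.03 ± 0.09). Vajk3 had 6 counts in the 3 Bon libraries together, with a 95% counting interval of -9.63 to -7.06 for its log2 ratio. Its order against Vajk2, v, y and Fa2h is therefore open. Other large falls were yellow (y, a pigmentation gene, -7.24 ± 0.04), Fa2h (a fatty acid hydroxylase, -7.12 ± 0.13), PH4alphaMP (a prolyl hydroxylase subunit, -7.04 ± 0.16), the multicopper oxidase gene Mco4 (-6.62 ± 0.14) and rho-6 (-6.08 ± 0.17). Among the rises, the receptor gene mthl8 went from 0.0667 CPM, near the level of 3 counts in a library, to 41.5 CPM (9.21 ± 0.16, adjusted p = 9.8e-15), and the neighbouring cytochrome P450 genes Cyp4p1 and Cyp4p2 rose by 8.35 ± 0.14 and 7.49 ± 0.08. In mCherry mthl8 and Cyp4p1 each had 8 counts over the 3 libraries, with counting intervals of 8.29 to 10.48 and 7.43 to 9.62. Each genotype is a single stock combination. For such rises from near absence, a response to Bon and a difference between the stocks cannot be told apart. Further rises were tpr (6.05 ± 0.26), the cuticle protein gene Cpr72Ea (from 131 to 4190 CPM, 5.00 ± 0.07), the odorant-binding protein gene Obp56a (4.08 ± 0.11) and drm, of the odd-skipped family (4.05 ± 0.15).

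By count, 2786 genes rose and 3009 fell, 5795 of 11068 (52.4%), in the edgeR quasi-likelihood test. Of these, 466 rises and 616 falls had an absolute log2 fold change of at least 1. The balance of rises and falls depended on scaling. With upper-quartile factors 3894 rose and 2323 fell, so that rises made up 62.6% of calls against 48.1%. In the authors' deposited table for this comparison, 2156 genes rose and 2469 fell, and 4545 of the 4568 calls that could be compared were also made here. Across genes the log2 fold changes correlated at 0.999 with those of that table.

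Eye genes moved apart by group. Of 21 tested genes of eye pigment synthesis and granules, 15 fell and 1 rose, and the same numbers held adjusted over the list alone (camera adjusted p = 0.000708, and adjusted p = 0.298 with an estimated correlation). With upper-quartile scaling 13 fell and 3 rose. They included v, cardinal (cd, -1.1 ± 0.03) and cinnabar (cn, kynurenine hydroxylase, -3.03 ± 0.07). Without y and v the list kept an adjusted p of 0.00311. All 4 lens and corneal genes fell, also when adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.298 with an estimated correlation). Crys, the lens crystallin, had -7.07 ± 0.29 (9 counts in the 3 Bon libraries, counting interval -8.25 to -6.19), and Cpr72Ec -2.34 ± 0.17. A further member, retinin, stood at 0.704 CPM in mCherry and had 0 counts in the Bon libraries, at least 9.16-fold lower against a floor of 3 counts in a library. The list's median was -4.70 as fitted and -2.77 with retinin at that bound.

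The other eye lists held members that moved both ways and did not pass the test as lists with the low-count filter and all libraries. Of 15 retinal determination genes, 7 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.974). Among the falls were so (-0.71 ± 0.03) and eya (-1.06 ± 0.05), which encode a transcription factor and its partner. Of 21 regulators of photoreceptor, cone and pigment cell fate, 8 rose and 8 fell (9 fell adjusted over the list alone; camera adjusted p = 0.905), with sv, the Pax2 homologue of cone and pigment cells, at -2.07 ± 0.04 and the homeobox gene B-H1 at -1.0 ± 0.04. Of 29 phototransduction and rhabdomere genes, 14 rose and 13 fell, as also adjusted over the list alone (camera adjusted p = 0.938). Here ninaC, which encodes a myosin of rhabdomeres, and Calx, a sodium-calcium exchanger gene, had -1.29 ± 0.03 and -1.52 ± 0.05. Of 13 genes of lattice cell adhesion and patterning, 3 rose and 6 fell (7 fell adjusted over the list alone; camera adjusted p = 0.266), with the immunoglobulin-domain genes sns and hbs at -1.49 ± 0.03 and -0.89 ± 0.03. Of 22 presynaptic and neuronal genes, 12 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.0668). Among them unc-13 rose by 0.73 ± 0.04, while Hdc, needed for histamine synthesis, had -1.3 ± 0.08. That list passed with no low-count filter (adjusted p = 0.0306), without mCherry replicate 3 (0.0226) and without Bon replicate 2 (0.0452).

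Genes of trichomes and cuticle moved both ways, in a comparison where 52.4% of all tested genes were past the threshold. None of their lists passed the camera test, while fry passed each of them but that of trichomes (fry adjusted p = 0.886). Of 23 tested effectors of trichomes and actin bristles, 12 rose and 9 fell, as also adjusted over the list alone (camera adjusted p = 0.34). The smallest p-values of the list were those of y, which fell, and of sha, which acts in hair formation and rose from 95.4 to 611 CPM (2.68 ± 0.05, adjusted p = 1.65e-13). Of 43 cuticle structural protein genes, 18 rose (19 adjusted over the list alone) and 16 fell (camera adjusted p = 0.974). Vajk4 had -5.36 ± 0.11, beside Vajk3. Of 23 chitin synthesis and remodelling genes, 7 rose and 12 fell, as also adjusted over the list alone (camera adjusted p = 0.336). The chitinase gene Cht5 went from 8150 to 1810 CPM (-2.17 ± 0.04), and Idgf4 had -2.84 ± 0.05. Of 16 tanning and melanin genes, 6 rose (7 adjusted over the list alone) and 5 fell (camera adjusted p = 0.905), with y and with t at -0.55 ± 0.03. Of 17 epidermal and head-cuticle fate regulators, 4 rose and 6 fell, as also adjusted over the list alone (camera adjusted p = 0.41), with Wnt6 at -1.78 ± 0.08 and inv at -1.33 ± 0.08. Of 8 proneural and sensory bristle genes, 4 rose and 1 fell (2 fell adjusted over the list alone; camera adjusted p = 0.811), with sv and with nompA at 0.58 ± 0.03.

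Signalling lists likewise did not pass the test with the low-count filter and all libraries. Of 14 E(spl) and Bearded complex Notch targets, 3 rose and 8 fell, as also adjusted over the list alone (camera adjusted p = 0.0668), with sv and with Hey at -4.21 ± 0.10. They passed with no low-count filter (adjusted p = 0.0228) and without Bon replicate 2 (0.0328). Of 21 EGFR pathway genes, 4 rose and 8 fell (9 fell adjusted over the list alone; camera adjusted p = 0.336), with the protease genes rho and ru at -1.21 ± 0.03 and -1.28 ± 0.04. Of 18 canonical Yki targets, 7 rose (8 adjusted over the list alone) and 7 fell (camera adjusted p = 0.904), with dlp at -1.48 ± 0.03 and the EGFR ligand gene vn at -1.82 ± 0.06. With upper-quartile scaling the Yki targets had 10 rises and 5 falls, the EGFR genes 8 and 8, the epidermal regulators 5 and 5 and the photoreceptor, cone and pigment cell regulators 10 and 8. Of 29 Hippo pathway components, 13 rose and 7 fell (camera adjusted p = 0.336), with Fbxl7 at -0.81 ± 0.04 and ds, an atypical cadherin gene, at 0.60 ± 0.04, and 17 rose with upper-quartile scaling. Of 16 planar cell polarity genes, 8 rose and 4 fell (camera adjusted p = 0.435), with ds and with mwh at 0.30 ± 0.03. The counts of these lists were the same adjusted over the list alone. Among 23 septate junction genes, 3 rose and 12 fell (camera adjusted p = 0.0668), with Gli at 0.58 ± 0.03 and Fas3 at -0.64 ± 0.03, and 8 fell with upper-quartile scaling. This list passed with no low-count filter (adjusted p = 0.0306) and without mCherry replicate 3 (0.0313). For 10 Wingless targets the counts were 4 and 5 (camera adjusted p = 0.905), with Wnt6 and with Notum at -0.54 ± 0.04, and for 22 ecdysone response genes 8 and 12 (camera adjusted p = 0.336), with ImpL2 at -2.10 ± 0.03 and E23 at -1.13 ± 0.04. Adjusted over the list alone, the counts of these 3 lists were also unchanged, and with upper-quartile scaling the Wingless targets had 4 rises and 4 falls.

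Among lists of growth, death and stress, 11 of 27 cell cycle genes rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 0.151). The cyclin-dependent kinase inhibitor gene dap fell by 2.28 ± 0.05 on the log2 scale, while CycA, a mitotic cyclin gene, rose by 1.11 ± 0.03. Of 16 apoptosis genes, 7 rose and 5 fell (camera adjusted p = 0.451), with Debcl at -0.57 ± 0.04 and the death inducer rpr at 1.03 ± 0.10, and 8 rises and 3 falls with upper-quartile scaling. Of 15 genes of JNK signalling and tissue stress, 6 rose and 6 fell (camera adjusted p = 0.743), with Mmp1 at 1.02 ± 0.04 and Ets21C at -2.36 ± 0.10, and 7 rose with upper-quartile scaling. For 19 heat shock and chaperone genes the counts were 6 and 8 (camera adjusted p = 0.905), with Hsp60A at 0.44 ± 0.02 and Hsp70Bb, a gene with near-identical copies, at -0.34 ± 0.03, and 7 rises and 7 falls with upper-quartile scaling. For 12 immunity genes they were 2 and 3 (camera adjusted p = 0.41), with PGRP-LB at -5.05 ± 0.10 and PGRP-SA at 0.90 ± 0.12. Each of these counts was the same adjusted over the list alone.

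Markers of other cell types and of sex were measured beside these groups. Of 13 glial markers, 1 rose and 6 fell (camera adjusted p = 0.266), with wrapper at -1.3 ± 0.03 and loco at -0.53 ± 0.03, and 2 rose with upper-quartile scaling. Of 13 hemocyte markers, 0 rose and 4 fell (camera adjusted p = 0.336), with SPARC at -0.91 ± 0.04 and vkg at -0.93 ± 0.05, while with upper-quartile scaling 3 rose and 4 fell. Of 15 brain and optic lobe neuron markers, 2 rose and 1 fell, the last being lost when adjusted over the list alone (camera adjusted p = 0.904), with bsh at 0.52 ± 0.04 and toy at 0.31 ± 0.04. For 15 muscle markers the counts were 0 and 3 (camera adjusted p = 0.905), with sls at -0.94 ± 0.06 and flr at -0.23 ± 0.03, for 11 fat body markers 1 and 1 (camera adjusted p = 0.932), with Lsp1gamma at -1.31 ± 0.21, and for 9 sex markers 3 and 0 (camera adjusted p = 0.102, and 0.0436 with no low-count filter). Yp3, on the last 2 of these lists, rose by 3.12 ± 0.10, and fru rose by 2.46 ± 0.12. Apart from the neuron markers, the counts were the same adjusted over the list alone. The median, mean and test direction differed in sign for 10 of the 32 lists, those of retinal determination, fate regulators, phototransduction, trichomes, proneural genes, cuticle structure, tanning, brain neurons, fat body and muscle. With a correlation estimated per list, 0 of 32 lists passed, and fry, which tests for movement in 1 direction, passed 27.

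With yki knocked down in Bon eyes, 17 of 23 trichome effectors, 11 of 16 planar polarity genes and 12 of 23 septate junction genes fell. At the same time 9 of 21 eye fate regulators, 6 of 14 Notch targets and 8 of 15 brain and optic lobe neuron markers rose. These lists passed the camera test with a preset correlation but not with an estimated correlation (adjusted p = 0.342 for trichomes and 0.443 for the others), and without chromosome 3 the calls of trichomes (0.0892) and eye fate regulators (0.266) ended. The largest fall by the naming rule was in mthl8 (3L, 22428 to 26308), from 41.5 to 0.116 CPM (log2 fold change -8.44 ± 0.15, adjusted p = 8.04e-14). Osi3 and Osi10, of the Osiris family of insect membrane proteins, had -3.67 ± 0.35 and -3.03 ± 0.15. Other falls were the NADPH oxidase gene Nox (-2.76 ± 0.09), the BMP ligand gene dpp (from 32.8 to 8.01 CPM, -2.03 ± 0.06), the serine protease gene Sp7 (-2.0 ± 0.08), Obp56a (-1.76 ± 0.09) and out (-1.75 ± 0.06). The largest such rise was in y (X, 356509 to 361245), from 4.47 ± 0.365 to 521 ± 10.1 CPM (6.87 ± 0.04, adjusted p = 1.21e-19). Dhc98D, a dynein heavy chain gene, rose by 2.12 ± 0.07. The transcription factor gene zld rose by 2.10 ± 0.45 (adjusted p = 0.0151), from 2.59 to 11 CPM with an SD of 5.98 CPM, and missed the threshold without Bon replicate 1 (2.09, adjusted p = 0.0566) or Bon replicate 2 (2.05, 0.0606). Mocs1, of molybdenum cofactor synthesis, rose by 2.03 ± 0.07, and the circadian regulator gene Clk by 1.98 ± 0.16. PGRP-LC, an immune receptor gene (1.55 ± 0.05), E(spl)mdelta-HLH, a Notch target (1.41 ± 0.07), and the cuticle gene Pcp (1.34 ± 0.09) followed.

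In this comparison 1251 genes rose and 1803 fell, 3054 of 11068 (27.6%), in the edgeR quasi-likelihood test, and 124 rises and 190 falls had an absolute log2 fold change of at least 1. With upper-quartile factors 1610 rose and 1468 fell, so that rises made up 52.3% of calls against 41.0%. The authors' deposited table had 1295 rises and 1321 falls, and 2368 of its 2604 calls that could be compared were also made here. Genes past the threshold with a log2 change of at least 1 made up 3.99% of the tested genes on chromosome 3 (195 of 4892), 1.79% on chromosome 2 (75 of 4182) and 2.3% on the X chromosome (43 of 1868). For Bon against mCherry these were 491 of 4892 genes on chromosome 3 and 439 of 4182 on chromosome 2.

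Members of the list of trichome and actin bristle effectors mostly fell. Of 23 tested members 17 fell and 3 rose (4 rose adjusted over the list alone; camera adjusted p = 7.2e-05, and adjusted p = 0.342 with an estimated correlation). The zona pellucida domain gene mey fell by 1.3 ± 0.03 on the log2 scale, and the actin-bundling gene f had -0.94 ± 0.03, from 371 to 193 CPM. Of the 3 rises 1 was y, and without y the adjusted p was 7.8e-07. Without members on chromosome 3 the list had 11 members and an adjusted p of 0.0892. Of 16 planar cell polarity genes, 11 fell (12 adjusted over the list alone) and 1 rose (camera adjusted p = 0.00336, adjusted p = 0.443 with an estimated correlation, 0.00472 without chromosome 3). The wing hair regulator gene mwh had -0.59 ± 0.03, the atypical cadherin gene ft -0.63 ± 0.04 and its ligand gene ds -0.37 ± 0.04. Of 23 septate junction genes, 12 fell and 1 rose, as also adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.443 with an estimated correlation, 0.0186 without chromosome 3). Their changes were small, with crim at -0.22 ± 0.03, Cont at -0.25 ± 0.03 and kune at -0.23 ± 0.03.

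Of 29 Hippo pathway components, a list that holds yki itself, 12 fell and 2 rose (3 rose adjusted over the list alone; camera adjusted p = 0.0356, and adjusted p = 0.488 with an estimated correlation). Beside yki, ex fell by 1.1 ± 0.06 on the log2 scale, from 88.4 to 41.4 CPM, and kibra had -0.46 ± 0.03. With upper-quartile scaling 11 fell and 4 rose. That call ended without mCherry replicate 2 (adjusted p = 0.0511), without Bon+yki-RNAi replicate 2 (0.0603) and without chromosome 3 (0.343). It also ended with the replicate block (camera adjusted p = 0.0609). Of 18 canonical Yki targets, which include ex and kibra, 10 fell and 4 rose (5 rose adjusted over the list alone), and the list did not pass (camera adjusted p = 0.102) but did with no low-count filter (0.0464). Their smallest p-values were those of kibra and ex. Diap1, a Yki target that inhibits apoptosis, fell by 0.22 ± 0.02 on the log2 scale, and egr, a TNF ligand gene, had 0.44 ± 0.05. The apoptosis list had 2 rises and 4 falls among 16 genes (3 and 5 adjusted over the list alone; camera adjusted p = 0.726). With upper-quartile scaling these were 3 rises and 2 falls.

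Of 43 cuticle structural protein genes, 14 fell and 5 rose (17 and 6 adjusted over the list alone; camera adjusted p = 0.0434, and adjusted p = 0.438 with an estimated correlation). Cpr49Ah had -0.64 ± 0.04 and Cpr49Ae -0.58 ± 0.04, while Pcp rose as above. That call was lost without mCherry replicate 1, without mCherry replicate 2, without Bon replicate 1, without Bon replicate 3 and without Bon+yki-RNAi replicate 1 (adjusted p = 0.0725, 0.088, 0.128, 0.0718 and 0.109), with no low-count filter (0.356) and without chromosome 3 (0.342). Of 23 chitin genes, 4 rose and 9 fell (11 fell adjusted over the list alone; camera adjusted p = 0.107), with Cht5 at 0.73 ± 0.04 and Idgf4 at 0.97 ± 0.06. Of 16 tanning and melanin genes, 2 rose and 5 fell (8 fell adjusted over the list alone; camera adjusted p = 0.186), with y and with laccase2 at -0.58 ± 0.04. Without y that list had an adjusted p of 0.0324.

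Members of eye fate lists that passed the threshold mostly rose, by small amounts. Of 21 regulators of photoreceptor, cone and pigment cell fate, 9 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.00365, adjusted p = 0.443 with an estimated correlation, 0.266 without chromosome 3). Here ct had 0.69 ± 0.05, sv 0.41 ± 0.04 and caup 0.27 ± 0.03, and with upper-quartile scaling 10 rose and 0 fell. Of 15 retinal determination genes, 7 rose and 0 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0321, adjusted p = 0.443 with an estimated correlation, 0.0892 without chromosome 3). Among them eya and toy each had 0.21, with standard errors of 0.05 and 0.04, and Optix 0.27 ± 0.06. That call ended without Bon replicate 3 (adjusted p = 0.074) and without Bon+yki-RNAi replicate 3 (0.052). Of 14 E(spl) and Bearded complex Notch targets, 6 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.00203, adjusted p = 0.443 with an estimated correlation, 0.0281 without chromosome 3), with E(spl)mdelta-HLH as above, E(spl)m3-HLH at 0.99 ± 0.06 and ct. Of 21 EGFR pathway genes, 9 rose (10 adjusted over the list alone) and 2 fell (camera adjusted p = 0.00593, adjusted p = 0.488 with an estimated correlation, 0.885 without chromosome 3). The feedback inhibitor gene sty rose by 0.28 ± 0.02, the protease gene ru by 0.41 ± 0.04 and the ligand gene vn by 0.71 ± 0.07.

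Of 21 eye pigment genes, 6 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.0488, adjusted p = 0.443 with an estimated correlation, 0.304 without chromosome 3). The list was led by v (from 0.223 to 5.72 CPM, 4.65 ± 0.14), with Pu at -0.52 ± 0.04 and w at 0.76 ± 0.05 (577, 173 and 292 CPM in mCherry, Bon and Bon+yki-RNAi). Without v the list's adjusted p was 0.124, and with no low-count filter 0.0562. Its call was also lost without any of the 3 mCherry libraries (adjusted p = 0.0627, 0.0876 and 0.0723 for replicates 1, 2 and 3). The same held without Bon replicate 2 (0.0542), Bon replicate 3 (0.0686) and Bon+yki-RNAi replicate 3 (0.0551), and with the replicate block (0.0772). Of 22 presynaptic and neuronal genes, 7 rose (14 adjusted over the list alone) and 2 fell (camera adjusted p = 0.00336, adjusted p = 0.488 with an estimated correlation, 0.0186 without chromosome 3), with unc-13 at -0.27 ± 0.04, Cadps at 0.18 ± 0.03 and cpx at 0.12 ± 0.03. With upper-quartile scaling 13 rose and 1 fell, and with fry the adjusted p was 0.074. Beside these, markers of brain and optic lobe neurons rose in 8 of 15 cases and fell in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.443 with an estimated correlation, 0.00472 without chromosome 3). Among them bsh had 0.25 ± 0.04, VGAT 0.44 ± 0.09 (from 10.9 to 14.6 CPM) and toy, also a retinal determination gene, 0.21 ± 0.04.

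The other lists did not pass in this comparison with all members, the low-count filter and all libraries. Of 29 phototransduction genes, 5 rose and 6 fell, as also adjusted over the list alone (camera adjusted p = 0.807), and with upper-quartile scaling 7 rose and 6 fell. The photoreceptor membrane protein gene chp fell by 1.33 ± 0.05 on the log2 scale, and Gbeta76C rose by 0.55 ± 0.03. The 4 lens genes had 1 rise, Cpr72Ec (1.23 ± 0.18), and 1 fall, Cpr66D (-0.50 ± 0.12; camera adjusted p = 0.359). Cpr66D missed the threshold without Bon+yki-RNAi replicate 1 (-0.44, adjusted p = 0.0564) or 2 (-0.48, 0.0555). Of 13 lattice adhesion genes, 4 rose (5 adjusted over the list alone) and 4 fell (camera adjusted p = 0.612), with sns at 0.33 ± 0.03 and ed at -0.30 ± 0.04. Of 17 epidermal fate regulators, 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.162), with Wnt6 at 1.01 ± 0.09 and wg at 0.39 ± 0.04, and of 8 proneural genes 2 rose (3 adjusted over the list alone) and 3 fell (camera adjusted p = 0.486), with sv and with neur at 0.22 ± 0.03. With upper-quartile scaling the proneural genes had 3 rises and 2 falls. Of 10 Wingless targets, 4 rose (5 adjusted over the list alone) and 2 fell (camera adjusted p = 0.0642), with Notum at 0.58 ± 0.04 and with Wnt6, and 1 fell with upper-quartile scaling. This list passed without chromosome 3 (5 members, adjusted p = 0.00921), with no low-count filter (0.0168) and without Bon replicate 2 (0.0363). Of 22 ecdysone response genes, 8 rose and 3 fell (camera adjusted p = 0.0909), with ImpE1 at -0.91 ± 0.03 and ImpE2 at -0.61 ± 0.03.

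For 27 cell cycle genes the counts were 3 rises and 4 falls (camera adjusted p = 0.888), with dap at 0.47 ± 0.06 and CycE at -0.33 ± 0.06. With upper-quartile scaling they were 3 and 3. Of 15 stress genes, 0 rose (1 adjusted over the list alone) and 4 fell (camera adjusted p = 0.344), with scaf at -0.65 ± 0.05 and GstD1 at -0.44 ± 0.03, and 1 rose with upper-quartile scaling. For 19 heat shock genes the counts were 2 and 4 (camera adjusted p = 0.419), with stv at -0.20 ± 0.04 and Hsp67Ba at 0.14 ± 0.03, and for 12 immunity genes 1 and 2 (camera adjusted p = 0.529), with PGRP-LF at 1.53 ± 0.16 and PGRP-SA at -1.16 ± 0.12. Of 13 hemocyte markers, 1 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.287), with Ppn at -0.28 ± 0.03 and SPARC at 0.22 ± 0.04, while with upper-quartile scaling 2 rose and 4 fell. Of 13 glial markers, 6 rose and 2 fell (camera adjusted p = 0.113), with Tret1-1 at -0.33 ± 0.08 and wrapper at -0.11 ± 0.03, which missed the threshold without Bon+yki-RNAi replicate 1 (-0.09, adjusted p = 0.0694). For 11 fat body markers the counts were 1 and 1 (camera adjusted p = 0.501), with Yp3 at -0.86 ± 0.08 and Lsp1gamma at 0.84 ± 0.22, the latter short of the threshold without Bon replicate 1 (0.73, adjusted p = 0.0621) or Bon+yki-RNAi replicate 1 (0.67, 0.071). The counts for 15 muscle markers were 2 and 0 (1 rise adjusted over the list alone; camera adjusted p = 0.26), with bt at 0.62 ± 0.10 and sls at 0.19 ± 0.06. The call of sls ended with no low-count filter (0.19, adjusted p = 0.0808) and without Bon replicate 3 (0.14, 0.0575), Bon+yki-RNAi replicate 1 (0.19, 0.0851) or 3 (0.18, 0.0925). For 9 sex markers the counts were 1 and 3 (camera adjusted p = 0.26), with dsx at -0.56 ± 0.05 and Yp3. Where no other count is given, that adjusted over the list alone was the same. The median, mean and test direction differed in sign for 5 of the 32 lists, those of phototransduction, lattice adhesion (median of 0), proneural genes, tanning and the cell cycle. With a correlation estimated per list, 0 of 32 passed, and fry passed 20.

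**Figure D2:**
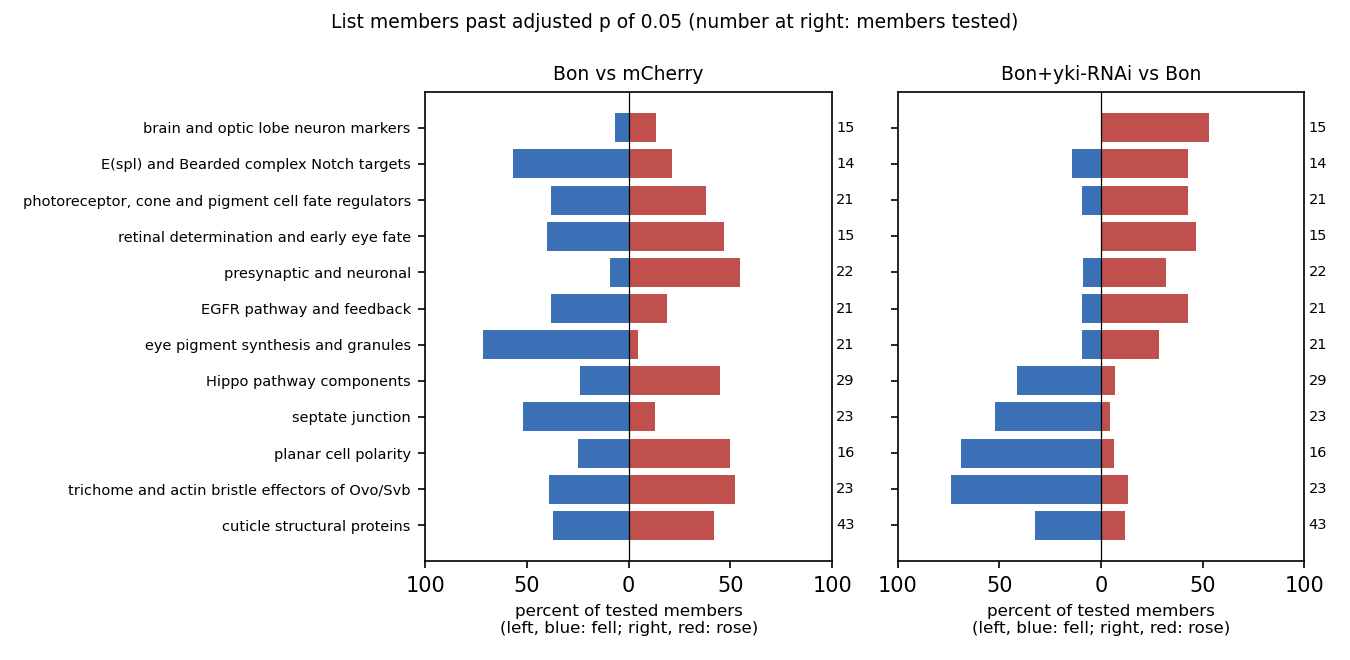
Share of the tested members of 12 gene lists that rose (red, right) or fell (blue, left) past an adjusted p of 0.05 in each comparison, in percent of the tested members, whose number stands at the right. The lists are those past the camera test for Bon+yki-RNAi against Bon, where 17 of 23 trichome effectors fell and 8 of 15 brain neuron markers rose.

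Which responses to Bon moved back when yki was knocked down was asked from the genes past the threshold in both comparisons, 2193 in all. No group had yki-RNAi without Bon, and none had Bon with a control RNAi construct. An effect of yki-RNAi that is independent of Bon, or of an added construct, therefore cannot be told apart from a lost response to Bon. Of these, 1354 moved in opposite directions, 787 that rose with Bon and fell with yki-RNAi and 567 that fell with Bon and rose with yki-RNAi. Independent lists of the same sizes would share 453.8 and 340.1 genes in these directions. In the same direction, 243 rose in both comparisons (314.9 from independent lists) and 596 fell in both (490.2). With a log2 fold change of at least 1 in both comparisons, 171 genes moved in opposite directions and 17 in the same one. Of the 1354 genes, 559 (41.3%) were not past the threshold between Bon+yki-RNAi and mCherry.

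Examples that rose with Bon and fell back were mthl8, Osi10 (from 1.11 to 11.7 and to 1.44 CPM in mCherry, Bon and Bon+yki-RNAi), Osi3 (13, 65.6 and 5.13 CPM), Sp7 (2.96, 18.8 and 4.70 CPM), Obp56a (33.3, 564 and 167 CPM) and the receptor gene Dh31-R (4.33, 36.3 and 11.2 CPM). Genes that fell with Bon and rose again were y (674, 4.47 and 521 CPM), Mocs1 (3L, 11070526 to 11073348; 21.4, 5.27 and 21.5 CPM), Dhc98D (86.6, 31.3 and 136 CPM), Pcp (12.3, 3.14 and 7.96 CPM), Gnpnat, an enzyme gene of chitin precursor synthesis (66.3, 15.3 and 36.8 CPM), and Cpr72Ec (59.8, 11.7 and 27.6 CPM). Of 24 tested genes within 50 kb of Mocs1, 0 were lower in Bon than in both other genotypes by a log2 value of at least 1. That count covers the neighbours only, since a difference between the stocks at Mocs1 itself could leave them unchanged. For these examples, mthl8, y and Mocs1 among them, a response to yki and a difference between the stocks cannot be told apart here.

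Because both comparisons use the Bon libraries, opposite signs arise without any effect. Across genes the log2 fold changes correlated at -0.42, against -0.48 in 20 simulations of unchanged groups, with genes not being independent replicates, and 54.8% of genes had opposite signs against 66.3%. The covariance was -0.159 against -0.0093 in the simulations, a difference of -0.149. The simulations made 0 opposite calls, but groups with no effect yield few calls at all, so that count does not measure the effect of shared libraries. The 3 Bon libraries were not split, so part of the excess over independent lists may come from sharing them. The share of tested genes with opposite changes of at least 1 in both comparisons was 2.04% on chromosome 3 and 1.22% on chromosome 2.

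**Figure D3:**
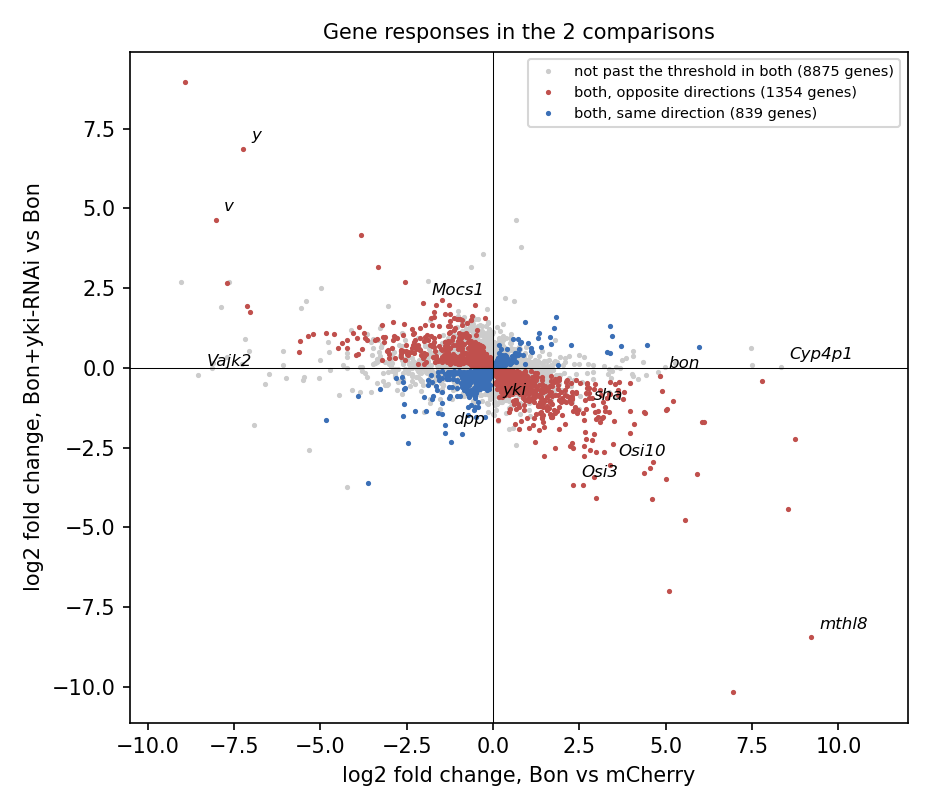
Log2 fold changes of 11068 genes for Bon against mCherry (horizontal axis) and Bon+yki-RNAi against Bon (vertical axis), with 1354 genes past the threshold in both and opposite in direction in red and 839 in the same direction in blue. The genes mthl8 and y lie far out in opposite corners, and points of genes with no count in a group take fitted values that depend on the prior count.

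Eyes with both manipulations differed from mCherry eyes about as widely as Bon eyes did. Against mCherry, bon stood at 4.58 ± 0.04 and yki at -1.06 ± 0.03, and Cyp4p1 and Cyp4p2 at 8.36 ± 0.14 and 7.59 ± 0.08. Vajk2 and Vajk3 had -8.75 ± 0.13 and -7.95 ± 0.22, Vajk3 with 6 counts in the 3 Bon+yki-RNAi libraries (counting interval -9.48 to -6.91), and for Cyp4p1 the interval was 7.44 to 9.64. The pigment genes y and v had -0.37 ± 0.03 and -3.38 ± 0.06, Dhc98D 0.65 ± 0.07 and zld 2.72 ± 0.50. Osi10 had 0.36 ± 0.23 (adjusted p = 0.199), and mthl8 stood at 0.116 CPM against 0.0667 CPM. Osi3 had -1.34 ± 0.41 (adjusted p = 0.0302) and missed the threshold without mCherry replicate 2 (-1.25, adjusted p = 0.0943) or 3 (-1.31, 0.0738), Bon replicate 2 (-1.33, 0.0507), and Bon+yki-RNAi replicate 2 (-1.08, 0.0808) or 3 (-1.25, 0.0879). In the edgeR quasi-likelihood test, 2773 genes rose and 3259 fell, 6032 in all (54.5%), and 341 rises and 623 falls had an absolute log2 fold change of at least 1. With upper-quartile factors 4252 rose and 2412 fell, so that rises made up 63.8% of calls against 46.0%.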

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

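The settings without chromosome 3 and without y and v were chosen only after the results were seen. Over the other settings that left every library in, with no fold minimum and no replicate block, 5029 to 6217 genes changed with Bon, 2625 to 3388 with yki-RNAi in Bon eyes, 5357 to 6664 between Bon+yki-RNAi and mCherry, and 1151 to 1386 in opposite directions. With a log2 fold change of at least 1 these were 1082, 314, 964 and 171 genes, which follows from the stricter criterion. Without genes of chromosome 3 they were 3205, 1549, 3398 and 635, with fewer genes tested. Leaving out 1 library at a time gave 5267 to 5725, 2291 to 3338, 5481 to 6181 and 1078 to 1444 genes, 4.82 to 4.89 for bon with Bon and -1.10 to -1.09 for yki with yki-RNAi.

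The list tests depended most on the settings. With an estimated correlation 0 lists passed for Bon against mCherry and 0 for Bon+yki-RNAi against Bon. Fry passed 27 and 20, which ask another question. Without list members on chromosome 3, where 30 lists could be tested and the lens list could not, there were 1 and 6 (5 of the 12, and Wingless targets), and with no low-count filter 6 for Bon against mCherry, where the cause was not tested. Leaving out 1 library gave 2 to 4 and 9 to 12 lists, with 4 for Bon against mCherry without mCherry replicate 3 or without Bon replicate 2. The replicate block gave 5986, 3448, 6266 and 1506 genes and 2 and 10 lists, and ended the calls of eye pigment (adjusted p = 0.0772) and Hippo components (0.0609) for Bon+yki-RNAi against Bon. Libraries with the same number correlated at -0.01 to 0.18 (2 of 9 pairs above 0.1), other pairs at -0.13 to 0.08, and 8 of 9 libraries correlated best with their own number, a hint from the data and not from the design.

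Of 189 log2 fold changes named in the text, 182 kept their direction and side of the threshold with the other scalings, test, filter, 6-library fit and replicate block and without each library, and 7 did not, namely those of yki, zld, Cpr66D, wrapper, Lsp1gamma and sls, and Osi3 against mCherry. Osi3 (-1.34, adjusted p = 0.0646) and sls (0.19, 0.0517) also missed the threshold with the replicate block. Over all 270 results that the naming rule admits for the first 2 comparisons, shown or not, 22 changed under some such setting. Of 4047 such tests, 42 lost a call, 5 gained one and 0 changed sign. In 1 more, retinin between Bon+yki-RNAi and Bon, the fold change became 0 without Bon+yki-RNAi replicate 2. Counts near 3 per library limit what is measured for such genes.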

Other observations

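The tests of a lower Bon level, of more responsive genes on chromosome 3, and of marker genes for y and v were chosen only after the results were seen, as were the gene families and the genes Osi4, Osi22, odd, sob, bowl, Cyp4p3, ftz and tut. The Osiris genes, a family of insect membrane proteins that lie mostly in 1 cluster on 3R, moved apart with Bon. Of 17 tested, 4 rose and 13 fell with Bon (median log2 fold change -1.46), and 0 rose and 11 fell when yki was knocked down in Bon eyes (median -0.99). With upper-quartile scaling 12 fell with Bon. Osi4 went from 195 to 6.79 CPM with Bon (-4.84 ± 0.14) and to 2.17 CPM with yki-RNAi (-1.65 ± 0.25), while Osi22 went from 10.3 to 92.8 CPM (3.16 ± 0.15) and back to 31.2 CPM (-1.57 ± 0.13).

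In the odd-skipped family of zinc finger genes, drm, sob and odd, which lie on 2L, rose with Bon from low levels. The values were 4.05 ± 0.15 for drm, 3.53 ± 0.15 for sob (from 0.327 to 3.81 CPM) and 4.20 ± 0.33 for odd (from 0.0698 CPM, 9 counts over 3 libraries, to 1.44 CPM, counting interval 3.30 to 5.41), against 0.25 ± 0.06 for bowl (from 186 to 221 CPM). With yki-RNAi 0 of the 4 rose and 2 fell, sob (-0.51 ± 0.10) and bowl (-0.40 ± 0.06). Cyp4p1 and Cyp4p2 stayed near their Bon level with yki-RNAi, and the third member of that cluster, Cyp4p3, stood at 0.0256, 1.09 and 1.2 CPM in mCherry, Bon and Bon+yki-RNAi. Whether a difference between the stocks at this cluster adds to these values was not tested.

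Genes with large changes between Bon+yki-RNAi and Bon were more frequent on chromosome 3 than on chromosome 2, by a ratio of shares of 2.22 (95% interval 1.71 to 2.89). This interval, like those of the other ratios of shares, counts each gene as an independent draw. Clustered genes such as the Osiris genes may move together, so the intervals may be too narrow. A ratio of at least 1.5 was predicted if the genotypes carried different third-chromosome homologues, so a difference in genetic background may account for part of these changes. The ratio for Bon against mCherry was 0.956 (0.846 to 1.08), which argues against genes of chromosome 3 being more responsive in any comparison. For Bon+yki-RNAi against mCherry it was 0.951 (0.835 to 1.08). Homologues that differ between Bon and Bon+yki-RNAi would set at least 1 of them apart from mCherry. Neither comparison with mCherry showed an excess on chromosome 3, which goes against a background difference. Both hold more changed genes, so a small excess could be hidden in them. An effect of yki on genes that happen to lie on chromosome 3 stays open and was not tested, because each genotype is a single stock combination. Among genes not past the threshold with Bon, the ratio was 3.73 (1.94 to 7.17).

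The genes changed in opposite directions could reflect a lower level of Bon in the Bon+yki-RNAi eyes. Of these 1354 genes, 126 (9.31%) differed from mCherry on the other side in Bon+yki-RNAi eyes, which a partly lower Bon level would not give where a gene responds steadily to Bon. The bon RNA itself stood at 174, 4980 and 4170 CPM in mCherry, Bon and Bon+yki-RNAi. Log2 changes of at least 1 in both comparisons were seen in 171 of the 1354 genes. For the 122 of them that rose with Bon, a response in proportion to bon RNA would not give such changes. For the 49 that fell with Bon it could, where the fall was deep. How steeply genes respond to Bon was not tested and Bon protein was not measured, so this explanation stays open. A third-chromosome homologue shared by mCherry and Bon+yki-RNAi but not by Bon predicted more such genes on chromosome 3. With changes of at least 1 in both comparisons the ratio was 1.68 (1.2 to 2.34). This cannot decide the question, because these genes are part of the Bon+yki-RNAi against Bon calls, whose ratio was 2.22. In the same direction the ratio was 1.57 (0.58 to 4.23), and for Bon against mCherry 0.956 (0.846 to 1.08). Such a homologue remains possible for part of the genes. A dependence of these responses on yki, which the design asks about, stays open.

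The genes y and v were far lower in Bon than in both other genotypes, at 674, 4.47 and 521 CPM for y and 59.3, 0.223 and 5.72 CPM for v. Copies of y or v carried as transgene markers by the mCherry and yki-RNAi stocks could give such a pattern, as a hypothesis. For v, expression to the same degree in both predicted a log2 difference under 1 between Bon+yki-RNAi and mCherry, and it was -3.38. This cannot exclude a v marker, because copies may be expressed unequally and the resident gene may itself respond to Bon. For y the difference of -0.37 leaves a marker open, because a response of y itself to yki predicts no other value. Of 112 genes that fell at least 8-fold with Bon, the median share of the log2 fall regained with yki-RNAi was 0.11, against 0.95 for y and 0.58 for v, a share on the log2 scale and not of the CPM. The larger part of the fall was regained by 7 of the 112 genes, y, v and ftz among them, so y and v were not alone.

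The gene w was lowest in Bon (577, 173 and 292 CPM) and also lower in Bon+yki-RNAi than in mCherry (-0.98 ± 0.05). Transgenes often carry w as a marker, and the number of copies per genotype is not given in the sources used here and was not tested. Other genes low in Bon alone were tut (3.64, 0.619 and 4.00 CPM) and ftz, which had 0 counts in Bon and was at least 18.8-fold higher in mCherry and 19.4-fold higher in Bon+yki-RNAi than 3 counts in a Bon library. Mocs1 was also low in Bon alone. Between Bon+yki-RNAi and mCherry the log2 difference was 0.01 ± 0.06 for Mocs1 and 0.06 ± 0.23 for ftz. Whether sequence carried by the stocks adds to the values of tut, ftz and Mocs1 was not tested.

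For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split gave 5795, 3054 and 6032 genes for Bon against mCherry, Bon+yki-RNAi against Bon and Bon+yki-RNAi against mCherry, the highest other split gave 0 in each, and 1 of 10 splits was thus as large. For the lists, Bon against mCherry gave 2 with the real split, 5 at most with another, and 6 of 10 splits gave as many. Bon+yki-RNAi against Bon gave 12, 7 at most with another, and 1 of 10 splits gave as many. Lists thus passed the test with a preset correlation in splits with 0 changed genes. A pass in that test alone therefore does not show that a list responds to the genotype. The mixed splits keep part of the difference between the genotypes, so they do not give the rate of false calls. For opposite changes, 3 of 100 splits drawn from 840 gave a result as large as 1354. The 2 besides the real one had 3828 and 4496 genes and put the mCherry libraries in the middle group. The other 97 gave 0, each with mixed genotypes, so this count sets the genotypes apart from random groups and says nothing on opposite directions as such. Counts several times the real one point to a structure of the samples, namely the distance of the mCherry libraries from the rest.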
